A study of Mus musculus with 12 samples.

How the data were processed

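RNA of primary mouse aortic smooth muscle cells was measured in 12 libraries, 4 each for regular growth medium, conditioned medium of naive bone marrow-derived macrophages and conditioned medium of macrophages treated with interferon gamma and lipopolysaccharide. Per the labels' protocols, polyadenylated RNA was made into stranded libraries with the Illumina Stranded mRNA Prep kit and sequenced on a NovaSeq X Plus in paired reads of 150 bp. Per the submitters' processing notes, expression was estimated with Salmon 1.10.1 against the mm10 build. The authors deposited estimated counts per gene (expected counts), 1 column per library, as whole numbers, which were taken as rounded Salmon estimates. How transcripts were summed to genes, the rounding and the annotation release are not given in the sources used here.

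The table held 55822 Ensembl gene identifiers. Of these, 51344 (92%) matched a symbol in GENCODE M21 by the identifier without its version, and 35 matched with the version, so the authors' annotation was another release. Identifiers without a symbol held 3.53 to 5.86% of the counts per library. Coordinates were taken from GENCODE M21 on GRCm38, which is the same build as mm10.

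Groups followed the sample titles. Columns were joined to the titles by their names, with M0 read as naive and M1 as IFNγ/LPS macrophages, the usual names of these states, which the labels do not spell out, and with the last digits read as the replicate number. Comparisons were IFNγ/LPS CM against naive CM, naive CM against regular medium and IFNγ/LPS CM against regular medium. Libraries of the same number in the titles were not treated as paired across groups. The correlation of their deviations from the group means was -0.0637 to 0.0679 over 12 pairs, none over the threshold of 0.1. This rule cannot exclude a weaker pairing, so the replicate number was also tried as a block.

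Analyses were run in R 4.3.3. Genes were kept by edgeR 4.0.16 filterByExpr with the group as factor, which left 16140 genes. Counts were scaled by TMM, with mean factors of 1.09 in regular medium, 1.09 in naive CM and 0.836 in IFNγ/LPS CM, and tested with the edgeR quasi-likelihood F-test (robust, two-sided) in 1 model of all 12 libraries with 9 residual degrees of freedom. The Benjamini-Hochberg adjusted p threshold was 0.05, and counts with a change of at least 2-fold are given beside. CPM are counts per 1000000 of the TMM-scaled total. The SE of a log2 fold change was its size over the square root of F and is approximate; for genes with at most 100 counts in the lower group the ratio of summed counts is given with an exact 95% interval instead. A group with no count was set at 3 counts over the group to give a lower bound. Intervals and bounds cover counting error only.

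Gene lists, 30 in number, were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from each list and with fry. They were contractile genes, structural matrix, matrix proteases and their inhibitors, type I and shared interferon genes, interferon gamma genes, MHC class I, MHC class II, NF-κB targets, chemokines, cytokines, complement and acute phase, nitric oxide and redox, cell cycle, cell cycle inhibitors and p53 targets, cell death, cholesterol synthesis, lipid handling, markers of macrophages, endothelium and adventitial fibroblasts, osteochondrogenic genes, TGF-β, serum response factor and YAP targets, smooth muscle phenotype, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, stress response and ribosomal proteins. The lists, the comparisons, the tests and the rule for named genes were chosen before the data were examined. A further 6 lists, given among the other observations, were chosen after the values were seen.

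Genes were named by rule in the first 2 comparisons: the 6 largest rises and 6 largest falls past the test with at least 5 CPM in the higher group, no overlap between libraries and a named symbol; from each list up to 3 called members without overlap that changed most in the main direction and 1 in the other; and 36 genes whatever their result. Some genes that the rule names are not reported here. The text names part of the list members, picked for the description after their values were seen, while the alternatives and the search for outlying libraries were run on 160 genes. Iigp1 and Pkm in the first comparison fall outside the rule and were chosen after their values were seen, as were the macrophage and structural genes named only among the other observations.

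The alternatives tried were DESeq2 size factors and library totals in place of TMM, no filter and a stricter filter (1 CPM in at least 4 libraries), the DESeq2 1.42.0 Wald test, limma-voom, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. A test against a minimum fold of 2 and a fit without the 2 shallowest libraries were added after the data were seen. The pipeline was tested on simulated data, in which 4 of 148 calls of the first comparison and 11 of 151 of the second were false. The gene test had 50 changed genes at each fold, far fewer than passed in the real data. In simulated lists camera found 10 of 10 changed lists and called 0 of 30 unchanged lists. Genes were drawn independently there, so this did not test camera under the correlation within real lists. Mapped reads were not used here.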

Results

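RNA was measured by sequencing in primary mouse aortic smooth muscle cells, the contractile cells of the artery wall, in 12 libraries of 3 groups with 4 libraries each. Cells of the first group, called naive CM, received conditioned medium from bone marrow-derived macrophages that had not been stimulated. Cells of the second group, called IFNγ/LPS CM, received medium from macrophages that had first been exposed to 20 ng/mL interferon gamma overnight and to 100 ng/mL lipopolysaccharide for 4 hours and had then been washed. The third group was kept in regular growth medium. Before the conditioned media were added the cells had been starved for 48 hours in 0.3% serum, and they stayed in the conditioned media for 24 hours. The conditioned media also held 0.3% serum and 10 ng/mL M-CSF, a growth factor for macrophages. The total estimated count per library averaged 46759268 ± 14222466 in regular medium, 45690380 ± 12462945 in naive CM and 42370785 ± 1941136 in IFNγ/LPS CM (mean ± SD, n = 4 each), with a range of 28097496 to 61493375 over the 12 libraries. The titles number the libraries of each group as biological replicates and do not say whether they came from separate animals or cultures, so the p-values measure the spread between these libraries, part of which may be technical.

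The libraries of IFNγ/LPS CM stood far apart from the others. The first principal component of log2 CPM (counts per 1000000) held 85.0% of the variance and separated IFNγ/LPS CM from both other groups, and the second held 4.64% and separated naive CM from regular medium. The correlation of log2 CPM across genes was 0.989 to 0.993 between libraries of one group, 0.980 to 0.988 between naive CM and regular medium and 0.864 to 0.869 between IFNγ/LPS CM and naive CM. Within regular medium replicate 4 stood somewhat apart, at 0.9885 to 0.989 with the other libraries, which reached 0.9903 to 0.9926 among themselves. The 50 most abundant genes held 22.6 ± 0.271% of the counts in IFNγ/LPS CM, against 18 ± 0.885% in naive CM and 19.1 ± 0.561% in regular medium (mean ± SD, n = 4 each). Assignment of the table's columns to the conditioned media rests on the usual names M0 for naive and M1 for IFNγ/LPS macrophages in the column names, and every direction given here depends on it.

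**Figure D1:**
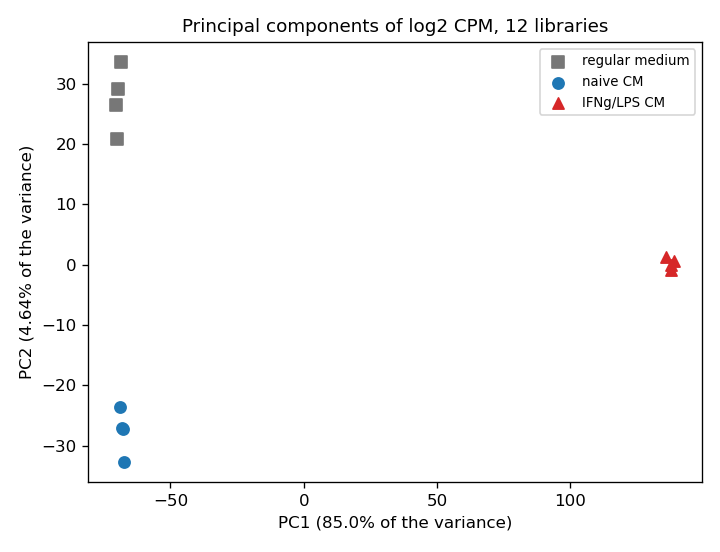
Principal components of log2 CPM over the genes tested; each point is 1 library, with PC1 (85.0% of the variance) on the horizontal and PC2 (4.64%) on the vertical axis. The 4 libraries of IFNγ/LPS CM lie apart from the other 8 on PC1, and naive CM and regular medium part on PC2.

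The first comparison asked how medium of IFNγ/LPS-treated macrophages changed the cells relative to medium of naive macrophages. Most interferon-induced, chemokine, acute phase and glycolysis genes rose. Some, such as the chemokines Ccl5 and Cxcl10, rose from near 0 to 896 and 6299 CPM. Contractile and cell cycle genes fell, the cell cycle genes without passing as a list when the correlation was estimated (adjusted p = 0.162). Gbp2, an interferon-induced GTPase, stood at 10410 ± 429 CPM in IFNγ/LPS CM against 15.1 ± 0.335 CPM in naive CM (690-fold; log2 fold change 9.43, SE 0.076, edgeR adjusted p = 8.98e-25; mean ± SD, n = 4 each). Mmp3, a matrix metalloproteinase, reached 21540 ± 547 CPM against 1114 ± 15 CPM (19.3-fold), and Acta2, smooth muscle actin, fell to 77.3 ± 3.60 CPM from 220 ± 8.05 CPM (2.85-fold lower). Of 16140 genes tested, 11611 passed an adjusted p of 0.05, 5830 higher and 5781 lower, and 4673 of these changed by at least 2-fold, 2246 higher and 2427 lower. Scaled by library totals alone, the median log2 fold change of all genes moved from 0.004 to -0.38 and the calls split into 3279 higher and 9371 lower, so small changes are relative to the scaling chosen.

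The genes with the largest rises, among those with a mean of at least 5 CPM in IFNγ/LPS CM, were nearly silent without it. Ccl5, a chemokine for T cells and monocytes, had no count in naive CM or in regular medium and 896 ± 22.1 CPM in IFNγ/LPS CM, at least 59800-fold higher than the 3 counts that a group at 0 allows. Cxcl9, an interferon gamma-induced chemokine, was likewise at 0 in both and at 660 ± 81.6 CPM, at least 44100-fold higher. Nos2, the inducible nitric oxide synthase, had 3 counts over the 4 naive CM libraries and 3765 ± 199 CPM in IFNγ/LPS CM, a ratio of 251000 with a 95% counting interval of 85900 to 1220000. Saa3, an acute phase protein, had 9 counts in naive CM and 6742 ± 108 CPM (ratio 150000, 78900 to 328000). Gbp10 and Serpina3f, at least 31500-fold and 31000-fold higher, belong to families of near-identical genes among which the counting can split reads, so their single values are uncertain. In the GRCm38 build with the GENCODE M21 annotation, Cxcl9 lies on chromosome 5 at 92321347 to 92328079 and Cxcl10 beside it at 92346638 to 92348889. Nos2 lies on chromosome 11 at 78920787 to 78960254, Mmp3 on chromosome 9 at 7445822 to 7455975 and Acta2 on chromosome 19 at 34241090 to 34255590. Each value is an estimated count per gene, not a count of reads over these intervals.

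Interferon-induced genes rose almost without exception. Of 50 genes of the type I and shared interferon list, 49 were higher and 1 was lower, with a median log2 fold change of 6.09 (camera adjusted p = 1.41e-173). Rsad2, an antiviral enzyme, stood at 1250 ± 26.1 CPM against 7 counts in naive CM (ratio 35700, counting interval 17300 to 88900). The member that fell was Ifi27, at 24.1 ± 1.97 CPM against 121 ± 6.50 CPM. All 30 genes of the interferon gamma list rose, with a median of 9.42, or 9.14 with the 5 genes that had no count in a group set at their lower bound (camera adjusted p = 6.63e-141). Iigp1, an immunity-related GTPase, rose 4450-fold to 5927 ± 234 CPM and Irf1, an interferon response factor, rose 40.5-fold to 1580 ± 59.5 CPM. Macrophage lineage markers moved in the same samples: of 30, 10 were measured, 9 higher and 1 lower (median 2.47, camera adjusted p = 6.98e-04, adjusted p = 0.0852 with an estimated correlation), and they are described again with the other cell type markers.

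Antigen presentation genes rose with them. All 23 MHC class I and antigen processing genes were higher, with a median log2 fold change of 4.39 (camera adjusted p = 4.31e-70). Nlrc5, a transactivator of MHC class I genes, reached 510 ± 11.2 CPM against 0.751 ± 0.225 CPM. Of 12 measured MHC class II genes 11 rose and 1 fell, with a median of 6.08, or 5.27 at the lower bound (camera adjusted p = 2.35e-19). Ciita, the transactivator of MHC class II genes, rose 146-fold to 122 ± 7.37 CPM, Cd74, the invariant chain, rose 787-fold to 466 ± 32.7 CPM and H2-Ab1 stood at 295 ± 20.4 CPM against 93 counts in naive CM (ratio 636, counting interval 519 to 788). The class II member that fell was Ifi30, a lysosomal thiol reductase, at 26.9 ± 0.605 CPM against 30.1 ± 1.32 CPM; without naive CM replicate 4 this call was lost (edgeR adjusted p = 0.0564).

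NF-κB target genes and most measured chemokine and complement or acute phase genes rose. All 38 NF-κB target genes were higher, with a median log2 fold change of 3.22 (camera adjusted p = 9.43e-55). Among them Ccl2, a monocyte chemokine, rose 2690-fold to 4834 ± 169 CPM, and Lcn2, an iron-siderophore binding protein, reached 2548 ± 201 CPM against 48 counts in naive CM (ratio 10600, counting interval 8020 to 14400). The adhesion molecules Icam1 and Vcam1 rose 89.8-fold and 6.21-fold, Vcam1 from an already high 680 ± 18.7 CPM to 4221 ± 94.2 CPM. Of 21 measured chemokine ligand genes 14 rose, 6 fell and 1 did not pass (median 5.45, camera adjusted p = 1.01e-25). Cxcl10, a chemokine for T cells, reached 6299 ± 364 CPM against 17 counts in naive CM (ratio 74200, counting interval 46400 to 127000), whereas Cxcl15 fell 14.2-fold from 259 ± 9.21 CPM to 18.3 ± 1.58 CPM. Of 23 complement and acute phase genes 19 rose, 2 fell and 2 did not pass (median 3.85, camera adjusted p = 1.98e-28). C3, the central complement component, rose 36.2-fold to 8963 ± 268 CPM, and Cd55, an inhibitor of complement on the cell surface, fell 2.85-fold.

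Cytokine genes moved less uniformly. Of 18 measured, 12 rose, 3 fell and 3 did not pass, with a median log2 fold change of 0.54 (camera adjusted p = 0.0323, adjusted p = 0.113 with an estimated correlation, camera adjusted p = 0.0642 with the replicate number as a block). With library totals 8 were higher and 5 lower (median 0.16). Il6 reached 66.1 ± 4.11 CPM against 23 counts in naive CM (ratio 576, counting interval 383 to 909), and Il33, an alarmin, fell 40.5-fold to 0.765 ± 0.158 CPM. Il1b and Ifng had no count in any library, Tnf had 6 counts and Ifnb1 had 5 counts in the 4 libraries of IFNγ/LPS CM, and neither had a count in the other groups, so transcripts of these 4 cytokines were not detectable or nearly so at this depth.

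Glycolysis and hypoxia response genes rose together, 29 of 31 higher and 2 not past the test, with a median log2 fold change of 2.52 (camera adjusted p = 6.93e-32). Pkm, pyruvate kinase, rose 3.20-fold to 6334 ± 172 CPM from 1981 ± 58.5 CPM, Egln3, an oxygen-sensing hydroxylase, rose 43.4-fold to 152 ± 9.09 CPM and Car9, a carbonic anhydrase, rose 37.2-fold to 28.1 ± 0.820 CPM. Of 28 unfolded protein and integrated stress response genes 24 rose and 4 fell (median 0.80, camera adjusted p = 2.91e-05). With library totals 20 were higher and 5 lower (median 0.41). Ero1l, an oxidase of the endoplasmic reticulum, rose 33.6-fold to 2851 ± 63.5 CPM, and Phgdh, which opens serine synthesis, fell 3.39-fold. Of 24 nitric oxide, oxidant and antioxidant genes 18 rose, 5 fell and 1 did not pass (median 0.95, camera adjusted p = 6.65e-08, adjusted p = 0.0643 with an estimated correlation). With library totals 15 were higher and 8 lower (median 0.57). Cybb, a subunit of the NADPH oxidase, rose 124-fold to 785 ± 21.7 CPM, and Gclc, which limits glutathione synthesis, fell 5.36-fold to 111 ± 3.07 CPM. Of 25 pyroptosis, necroptosis and apoptosis genes 24 rose and 1 fell (median 1.89, camera adjusted p = 2.03e-18). Zbp1, a nucleic acid sensor of necroptosis, rose from 17 counts in naive CM (ratio 2560, counting interval 1600 to 4390), and Fas, a death receptor, rose 7.59-fold.

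Contractile genes fell. Of 26 measured members of the smooth muscle contractile list 20 were lower, 2 were higher and 4 did not pass. The median log2 fold change was -1.52 (camera adjusted p = 1.21e-05, adjusted p = 0.0482 with an estimated correlation). Tagln, which encodes transgelin, stood at 0.550 ± 0.0315 CPM against 10.8 ± 1.78 CPM, a ratio of 20.1 with a counting interval of 16.1 to 25.6. Myocd, a coactivator of contractile genes, fell 5.51-fold to 0.914 ± 0.149 CPM. Myh11, smooth muscle myosin, fell from 0.592 ± 0.175 CPM to 0.203 ± 0.10 CPM, and Cnn1, calponin, was at 0.0553 ± 0.0597 CPM against 0.149 ± 0.0673 CPM and did not pass (log2 fold change -1.40, edgeR adjusted p = 0.0528). Cnn1 did pass in 5 of 15 alternatives, among them without IFNγ/LPS CM replicate 3 (log2 fold change -2.33, edgeR adjusted p = 0.00978). Mylk, the myosin light chain kinase, rose 2.12-fold from 0.732 ± 0.0965 CPM to 1.54 ± 0.409 CPM. Myh11 and Cnn1 were low already in regular medium, where Myh11 stood at 0.717 ± 0.180 CPM and Cnn1 at 0.276 ± 0.0553 CPM.

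Of 38 structural matrix genes 16 were higher, 16 were lower and 6 did not pass (median log2 fold change -0.02, camera adjusted p = 0.406). With library totals 13 were higher and 21 lower (median -0.40). Col3a1, a fibrillar collagen, fell 21.7-fold to 15.2 ± 2.00 CPM and Eln, elastin, fell 10.3-fold to 15.6 ± 0.584 CPM. By contrast, Lox, which crosslinks both, rose 3.97-fold to 1077 ± 72.0 CPM and Col18a1 rose 19.4-fold. Col1a1 was at 511 ± 62.7 CPM against 455 ± 46.3 CPM and did not pass (edgeR adjusted p = 0.505). Of 23 extracellular proteases 15 rose, 7 fell and 1 did not pass (median 0.51, camera adjusted p = 0.00496, adjusted p = 0.0411 with an estimated correlation). With library totals 12 were higher and 8 lower (median 0.12). Beside Mmp3, the collagenase Mmp13 rose 44.6-fold to 244 ± 15 CPM. By contrast, Adamts15 fell from 3.18 ± 0.394 CPM to 0.201 ± 0.157 CPM. Mmp9 had 5 counts in naive CM and 22 counts in IFNγ/LPS CM and was too low to be tested. Of 11 protease inhibitors 5 rose, 4 fell and 2 did not pass; their median was -0.08 while their mean was 1.44, and the list did not pass (camera adjusted p = 0.166; 5 higher and 6 lower with library totals). Its member Timp1, an inhibitor of metalloproteinases, rose 23.9-fold to 1597 ± 71.4 CPM.

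Cell cycle genes fell in all 44 measured members, with a median log2 fold change of -1.96 (camera adjusted p = 1.48e-14, adjusted p = 0.162 with an estimated correlation). Mki67, the proliferation marker, fell 9.08-fold from 249 ± 12.0 CPM to 27.5 ± 6.26 CPM (log2 fold change -3.18, SE 0.139, edgeR adjusted p = 2.91e-09), and Cenpf, a kinetochore protein, fell 17.7-fold from 155 ± 2.29 CPM to 8.75 ± 1.44 CPM. Of 25 cell cycle inhibitor and p53 target genes 18 rose, 5 fell and 2 did not pass (median 0.96, camera adjusted p = 0.00336, adjusted p = 0.162 with an estimated correlation). With library totals 15 were higher and 6 lower (median 0.57). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 5.19-fold to 225 ± 15.4 CPM, and Cdkn2c, another such inhibitor, fell 6.23-fold.

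Lipid genes also moved. Of 21 genes of cholesterol efflux, lipid uptake and lipid handling 13 rose, 4 fell and 4 did not pass (median log2 fold change 0.71, camera adjusted p = 0.0028). With library totals 12 were higher and 7 lower (median 0.32). Ch25h, which makes an oxysterol, reached 150 ± 8.38 CPM against 99 counts in naive CM (ratio 304, counting interval 249 to 374), and Olr1, an oxidised lipoprotein receptor, reached 28.6 ± 2.20 CPM against 59 counts (ratio 96.7, 74.8 to 127), while Fabp5, a fatty acid binding protein, fell 15.4-fold to 5.80 ± 0.584 CPM. Of 26 cholesterol synthesis genes 17 fell, 4 rose and 5 did not pass (median -0.71, camera adjusted p = 0.0410, adjusted p = 0.639 with an estimated correlation). With library totals 23 were lower and 1 was higher (median -1.10). Insig1, a regulator of the pathway, fell 2.66-fold to 118 ± 9.99 CPM. The list lost its call with the stricter filter on low counts (camera adjusted p = 0.0596) and without IFNγ/LPS CM replicate 4 (camera adjusted p = 0.0513).

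Markers of other cell types did not move as one. Among the 10 measured macrophage markers 9 rose: Mpeg1, a perforin-like protein, stood at 874 ± 50.6 CPM against 65 counts in naive CM (ratio 2690, counting interval 2110 to 3490), whereas Lcp1 fell, and 20 of the 30 markers were not tested because of low counts. Of 9 measured endothelial markers 4 rose, 3 fell and 2 did not pass (camera adjusted p = 0.598), with a median log2 fold change of 0.08 that became -0.30 with library totals. Of 12 adventitial fibroblast markers 9 fell and 3 rose (median -1.39, camera adjusted p = 0.129): Scara5, a scavenger receptor, stood at 0.0762 ± 0.0830 CPM against 18.8 ± 1.49 CPM (ratio 245, counting interval 137 to 491), while Ly6a, a surface protein of progenitor cells, rose 11.1-fold to 2379 ± 138 CPM. Of 13 osteochondrogenic genes 10 fell, 2 rose and 1 did not pass (median -1.13, camera adjusted p = 0.0863). Sox9, a chondrogenic transcription factor, fell 5.76-fold and Runx1 rose 15.6-fold.

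The other lists held genes that changed in both directions. Of 27 regulators and markers of smooth muscle phenotype 14 rose, 10 fell and 3 did not pass (median log2 fold change 0.28, and -0.11 with library totals, camera adjusted p = 0.296). Hey2, a Notch target, fell 17.1-fold, and Klf4 was 162 ± 10.9 CPM against 199 ± 7.31 CPM (edgeR adjusted p = 0.0159, or 0.058 without the 2 shallowest libraries). Of 28 TGF-β pathway genes 12 rose, 11 fell and 5 did not pass (median 0.001, mean 0.18 and camera direction down, median -0.39 with library totals, camera adjusted p = 0.723), with Ltbp2, which binds latent complexes of the pathway, 55.9-fold higher. Of 27 serum response factor and YAP targets 11 rose, 13 fell and 3 did not pass (median -0.008, mean 0.18 and camera direction down, camera adjusted p = 0.129), with Ccn2, a matricellular growth factor, 10.1-fold lower at 83.6 ± 9.53 CPM. Of 36 nuclear oxidative phosphorylation genes 23 fell, 4 rose and 9 did not pass (median -0.21, camera adjusted p = 0.172, or 0.0305 with library totals). Mitochondrially encoded genes, 4 lower and 1 higher of 13, did not pass as a list (median -0.28, camera adjusted p = 0.468); its higher member mt-Co1 was at 6888 ± 464 CPM against 5987 ± 706 CPM (log2 fold change 0.20, edgeR adjusted p = 0.0239), lost its call in 5 of 17 alternatives and turned lower with library totals (log2 fold change -0.18). Ribosomal protein genes, 15 lower and 7 higher of 40, did not pass either (median -0.09, camera adjusted p = 0.471). These counts depend on the scaling. With library totals 36 ribosomal protein genes were lower and 1 was higher (median -0.48). Of the mitochondrially encoded genes 10 were then lower and none higher (median -0.67). The counts with library totals were 33 lower and 1 higher for the oxidative phosphorylation list. They were 15 lower and 8 higher for the serum response factor and YAP targets, 15 lower and 10 higher for the TGF-β pathway and 12 lower and 12 higher for the smooth muscle phenotype list. Adjusted over the list alone, 23 of the 30 lists had as many changed members as over all genes; the counts were 24 for the contractile, 21 for the chemokine, 18 for the lipid handling, 25 for the serum response factor and YAP, 25 for the smooth muscle phenotype, 28 for the oxidative phosphorylation and 21 for the ribosomal protein list.

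Among single genes, Elobl fell from 96.4 ± 3.29 CPM to 0.238 ± 0.0637 CPM (ratio 403, counting interval 288 to 582), Wscd2 from 7.48 ± 0.453 CPM to 0.0496 ± 0.0148 CPM (ratio 152, 73.5 to 378) and Pipox, a peroxisomal oxidase, from 6.90 ± 0.669 CPM to 0.0770 ± 0.0342 CPM (ratio 89.9, 50.1 to 180). Aldh1a7, an aldehyde dehydrogenase, fell 97.8-fold from 109 ± 7.25 CPM to 1.12 ± 0.116 CPM.

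Across the comparison, 19 of the 30 lists passed camera at its preset correlation, 16 up and 3 down, and 13 passed with an estimated correlation. The libraries of the groups did not overlap in 69.5% of the genes tested, where chance alone would give 2.86%. In data simulated for this comparison the test recovered 70% of genes changed 1.5-fold, 74% of those changed 2-fold and 98% of those changed 4-fold. There, 50 of 16140 genes were changed at each fold, far fewer than passed here. These shares may therefore differ in the real data.

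**Figure D2:**
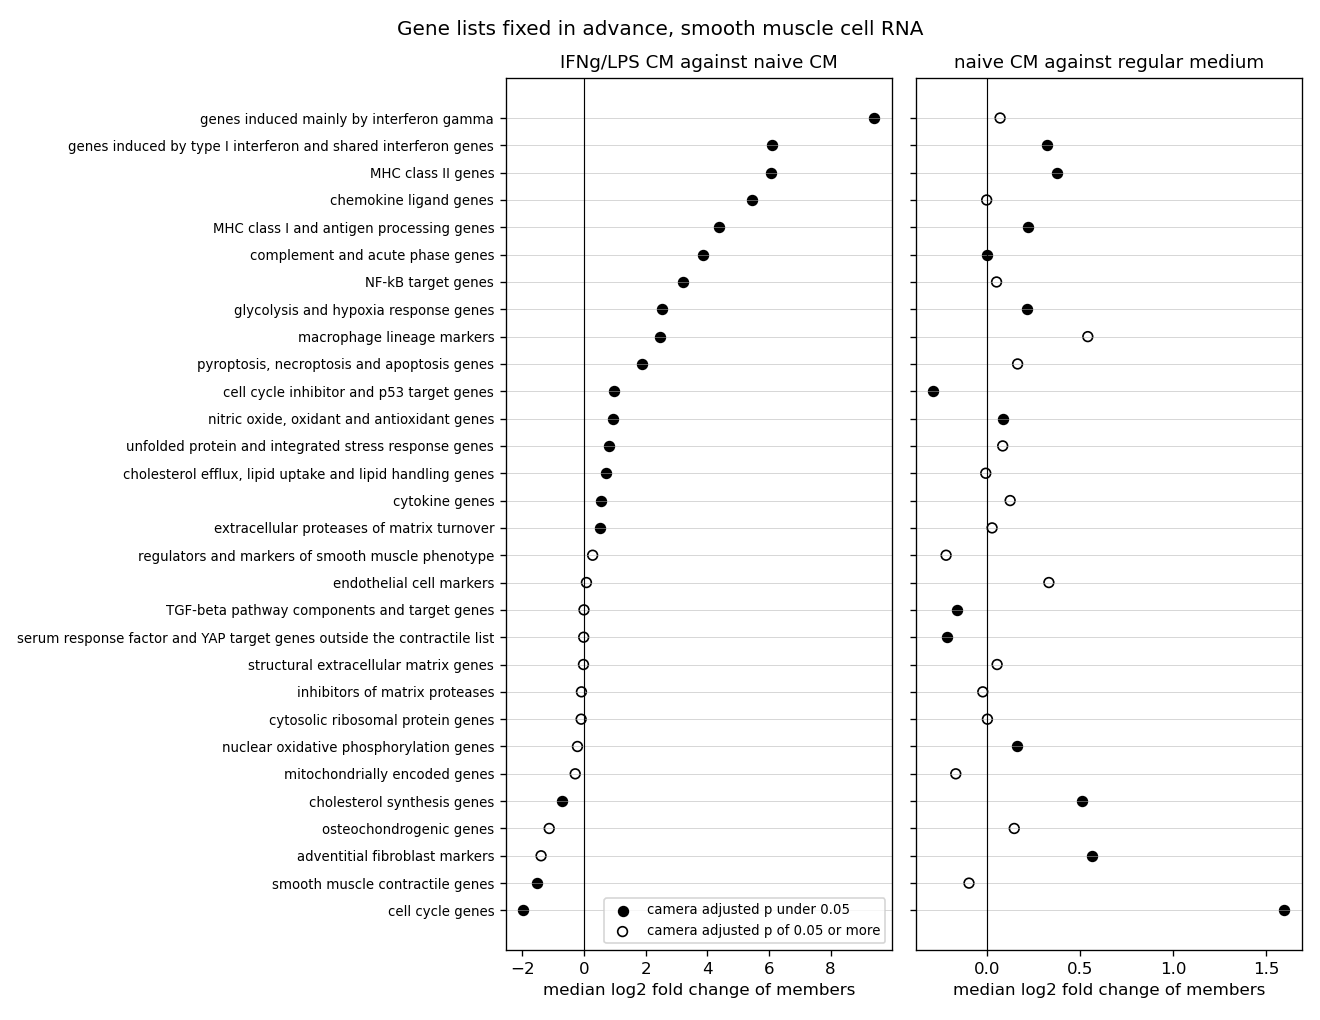
Median log2 fold change of the measured members of each of the 30 gene lists, on the left for IFNγ/LPS CM against naive CM and on the right for naive CM against regular medium, on axes of different range; filled points passed camera at an adjusted p of 0.05. On the left the interferon gamma list lies highest, at 9.42, and the cell cycle list lowest, at -1.96; on the right the cell cycle list lies highest, at 1.60. With library totals the left medians of the endothelial, TGF-β and smooth muscle phenotype lists turn negative.

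The second comparison set cells in naive CM against cells in regular medium. The labels used here give neither the serum content of the regular medium nor whether those cells were starved. The comparison may therefore join effects of low serum and starvation with those of macrophage medium and M-CSF. Cell cycle genes were higher in naive CM: Mki67 stood at 249 ± 12.0 CPM against 67.8 ± 6.33 CPM (3.67-fold; log2 fold change 1.88, SE 0.129, edgeR adjusted p = 1.41e-06; mean ± SD, n = 4 each) and Cenpf at 155 ± 2.29 CPM against 32.3 ± 1.97 CPM (4.80-fold). Cholesterol synthesis and glycolysis genes rose by smaller steps, and neither list passed with an estimated correlation (adjusted p = 0.269 and 0.23). Tagln fell from 31.6 ± 12.4 CPM to 10.8 ± 1.78 CPM (2.92-fold) and Acta2 from 280 ± 29.9 CPM to 220 ± 8.05 CPM. Of 16140 genes tested 5594 passed, 2949 higher and 2645 lower, of which 617 changed by at least 2-fold, 464 higher and 153 lower; with library totals the split was 2924 higher and 2593 lower.

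Of 44 cell cycle genes 42 rose and 2 did not pass, with a median log2 fold change of 1.60 (camera adjusted p = 6.98e-85, adjusted p = 0.0433 with an estimated correlation, 42 adjusted over the list alone). Cdc20, an activator of the anaphase complex, rose 4.67-fold to 80.7 ± 4.89 CPM and Kif20a, a mitotic kinesin, rose 4.58-fold. Of 25 cell cycle inhibitor and p53 target genes 10 fell, 2 rose and 13 did not pass (median -0.29, camera adjusted p = 0.00618, adjusted p = 0.269 with an estimated correlation, 13 adjusted over the list alone). In regular medium replicate 4 stood above the other 3 in the mean of this list. Without it the median was -0.18 (camera adjusted p = 0.0159). Cdkn1a fell from 62.6 ± 7.67 CPM to 43.3 ± 2.81 CPM and Pmaip1, the apoptosis regulator Noxa, fell 2.00-fold. Cdkn2c rose 2.15-fold. Adventitial fibroblast markers moved in the same samples, 7 higher, 3 lower and 2 not past the test of 12 (median 0.57, camera adjusted p = 0.0104, adjusted p = 0.126 with an estimated correlation, camera adjusted p = 0.057 with the replicate number as a block, 10 adjusted over the list alone). Dpt, a matrix protein, rose 3.98-fold to 9.87 ± 0.491 CPM and Ly6a rose 3.09-fold. Smoc2, a matrix calcium-binding protein, fell 3.65-fold from 107 ± 5.45 CPM to 29.2 ± 3.52 CPM.

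Of 26 cholesterol synthesis genes 20 rose, none fell and 6 did not pass (median log2 fold change 0.51, camera adjusted p = 2.11e-08, adjusted p = 0.269 with an estimated correlation, 23 adjusted over the list alone). Fdps, which makes farnesyl diphosphate, rose 1.83-fold to 90.2 ± 11.3 CPM. Of 31 glycolysis and hypoxia response genes 17 rose, 7 fell and 7 did not pass (median 0.21, camera adjusted p = 3.07e-07, adjusted p = 0.23 with an estimated correlation, 26 adjusted over the list alone), with Pkm 2.21-fold higher at 1981 ± 58.5 CPM and Pgk1, phosphoglycerate kinase, 2.17-fold higher at 415 ± 30.4 CPM. Of 36 nuclear oxidative phosphorylation genes 19 rose and 17 did not pass (median 0.16, camera adjusted p = 0.00208, adjusted p = 0.331 with an estimated correlation, 23 adjusted over the list alone), with Cox7a2, a cytochrome c oxidase subunit, 1.31-fold higher. Of 24 nitric oxide, oxidant and antioxidant genes 9 rose, 3 fell and 12 did not pass (median 0.09, or 0.07 at the lower bound, camera adjusted p = 0.00208, adjusted p = 0.319 with an estimated correlation, 15 adjusted over the list alone). Gclc rose 2.47-fold to 595 ± 29.6 CPM and Nqo1, a quinone reductase, rose 2.51-fold to 72.8 ± 2.61 CPM.

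Of 50 type I and shared interferon genes 27 rose, 4 fell and 19 did not pass (median log2 fold change 0.33, camera adjusted p = 4.80e-06, adjusted p = 0.0784 with an estimated correlation, 35 adjusted over the list alone), with Ifi27l2a 3.85-fold higher at 6.40 ± 0.855 CPM. Of 23 MHC class I genes 13 rose, 3 fell and 7 did not pass (median 0.22, camera adjusted p = 0.0105, adjusted p = 0.269 with an estimated correlation, 18 adjusted over the list alone). Psmb9, an immunoproteasome subunit, rose 1.68-fold and Nlrc5 fell 1.78-fold. Of 12 MHC class II genes 6 rose, 1 fell and 5 did not pass (median 0.38, camera adjusted p = 0.0200, adjusted p = 0.331 with an estimated correlation, 7 adjusted over the list alone), with Ciita at 0.865 ± 0.220 CPM against 52 counts in regular medium (ratio 3.25, counting interval 2.36 to 4.53). Of 23 complement and acute phase genes 7 rose, 5 fell and 11 did not pass (12 adjusted over the list alone); their median was 0.00 and their mean 0.39, with a camera adjusted p of 0.0154, an adjusted p = 0.269 with an estimated correlation, a camera adjusted p of 0.435 with the replicate number as a block and a camera adjusted p of 0.054 without regular medium replicate 4. C4b, a complement component, rose 5.15-fold to 9.02 ± 0.202 CPM and C3 rose 1.75-fold to 248 ± 8.66 CPM.

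Serum response factor and YAP targets fell, 11 lower, 2 higher and 14 not past the test of 27 (median log2 fold change -0.21, camera adjusted p = 0.00121, adjusted p = 0.269 with an estimated correlation, 13 adjusted over the list alone). Fhl2, a LIM-domain coactivator, fell 1.72-fold and Zyx, zyxin of focal adhesions, fell 1.45-fold to 263 ± 4.61 CPM. By contrast, Ccn1, a matricellular protein, rose 1.37-fold. Of 28 TGF-β pathway genes 13 fell, 3 rose and 12 did not pass (median -0.16, camera adjusted p = 0.0104, adjusted p = 0.23 with an estimated correlation, 16 adjusted over the list alone), with Ltbp4 1.66-fold lower at 115 ± 2.81 CPM and Ccn2 1.39-fold lower at 844 ± 44.2 CPM.

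The remaining 17 lists did not pass camera in this comparison. Contractile genes, 9 higher and 7 lower of 26, had a median log2 fold change of -0.10 (camera adjusted p = 0.389, 17 adjusted over the list alone), and structural matrix genes, 14 higher and 9 lower of 38, a median of 0.06 (camera adjusted p = 0.585, 24 adjusted over the list alone). In these lists Lmod1, an actin nucleator, rose 1.52-fold and Col3a1 rose 1.74-fold to 329 ± 20.8 CPM. By contrast, Eln fell 1.44-fold to 161 ± 12.1 CPM and Tnc, tenascin C, fell 2.09-fold. Proteases, 10 higher and 5 lower of 23 (median 0.03, camera adjusted p = 0.259, 16 adjusted over the list alone), held Mmp3, 2.08-fold higher at 1114 ± 15 CPM. Protease inhibitors, 4 higher and 1 lower of 11, had a median of -0.02 and a mean of 0.41 (camera adjusted p = 0.0643, and 0.0369 without regular medium replicate 4 and 0.0256 without naive CM replicate 1, 5 adjusted over the list alone), with Timp1 2.10-fold higher. Interferon gamma genes, 10 higher and 1 lower of 30, had a median of 0.07 (camera adjusted p = 0.126, 11 adjusted over the list alone), NF-κB targets, 9 higher and 4 lower of 38, a median of 0.05 (camera adjusted p = 0.328, 13 adjusted over the list alone) and chemokines, 6 higher and 2 lower of 21, a median of 0.00 (camera adjusted p = 0.179, 8 adjusted over the list alone), with Cxcl15 2.11-fold higher. Cytokines, 4 higher and 4 lower of 18, had a median of 0.13 and a mean of -0.06 (camera adjusted p = 0.739, 8 adjusted over the list alone), with Il33 2.40-fold higher and Csf1 1.46-fold lower. Smooth muscle phenotype genes, 4 higher and 13 lower of 27, had a median of -0.22 (camera adjusted p = 0.138, and 0.0167 with the replicate number as a block and 0.0493 without regular medium replicate 1, 20 adjusted over the list alone), with Klf5, a Krüppel-like factor, 1.95-fold lower.

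Cell death genes, 7 higher and 3 lower of 25, had a median log2 fold change of 0.17 (camera adjusted p = 0.292, 10 adjusted over the list alone), lipid handling genes, 8 higher and 4 lower of 21, a median of -0.005 and a mean of 0.09 (camera adjusted p = 1, 14 adjusted over the list alone), and stress response genes, 13 higher and 7 lower of 28, a median of 0.09 (camera adjusted p = 0.328, 22 adjusted over the list alone). Macrophage markers, 3 higher and none lower of 10, had a median of 0.54 (camera adjusted p = 0.133, 3 adjusted over the list alone), with Cd53, a leukocyte tetraspanin, at 8.22 ± 0.958 CPM against 3.54 ± 0.287 CPM. Endothelial markers, 1 lower of 9 (median 0.33, camera adjusted p = 0.892, 1 adjusted over the list alone), and osteochondrogenic genes, 2 higher and 3 lower of 13 (median 0.15, camera adjusted p = 0.328, 6 adjusted over the list alone), did not pass; Spp1, osteopontin, rose 4.50-fold to 94.3 ± 8.84 CPM. Mitochondrially encoded genes, 1 higher and 3 lower of 13 (median -0.17, camera adjusted p = 0.292, 4 adjusted over the list alone), and ribosomal protein genes, 6 higher and 5 lower of 40, did not pass; the ribosomal median was 0.004 and mean 0.01 with a camera direction of down (camera adjusted p = 1, 11 adjusted over the list alone).

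Among the genes named whatever their result, Vcam1 rose 1.40-fold to 680 ± 18.7 CPM, Gbp2 1.21-fold to 15.1 ± 0.335 CPM, Irf1 1.13-fold to 39.1 ± 1.01 CPM and Mmp13 1.49-fold to 5.46 ± 0.673 CPM. Lox fell 1.40-fold to 271 ± 24.7 CPM and Myocd 1.24-fold to 5.03 ± 0.377 CPM. Lcn2 had 48 counts against 5 counts in regular medium (ratio 9.83, counting interval 3.93 to 31.6). Klf4 (edgeR adjusted p = 0.342), Col1a1 (0.946), Myh11 (0.587), Cnn1 (0.181), Icam1 (0.0792), Ccl2 (0.404), Il6 (0.863), Cxcl10 (0.663), Saa3 (0.266) and Nos2 (0.114) did not pass, and Cxcl9 and Ccl5 had no count in either group.

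Several calls of this comparison were close to the threshold and were lost under some of the alternatives tried. Atf3, a stress-induced transcription factor, fell 1.78-fold to 3.75 ± 0.822 CPM and lost its call in 7 of 17 alternatives, as did Adm, adrenomedullin, 1.38-fold lower, and Tnfsf18, a cytokine, 1.53-fold lower. Hmox1, heme oxygenase, fell 1.68-fold to 31.7 ± 3.48 CPM and lost its call in 5 of 17, and Tgfbi, a matrix protein, was at 124 counts against 73 counts (ratio 1.74, counting interval 1.29 to 2.35) and lost it in 5 of 16. Bst2, an interferon-induced membrane protein, 1.32-fold lower, and mt-Nd6, 1.31-fold higher, lost their calls in 1 of 17 each.

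Among named gene models with a mean of at least 5 CPM in naive CM and no overlap between the libraries, the largest rises were those of Sprr2a2 and Sprr2a3, 7.43-fold to 278 ± 13.4 CPM and 7.94-fold to 16.9 ± 1.31 CPM, which encode small proline-rich proteins, are near-identical and are uncertain as separate values. Arhgef39 rose 6.90-fold, Npy4r 6.27-fold, Hist1h1a, a linker histone, 6.16-fold to 29.6 ± 2.20 CPM, and Pif1, a helicase, 5.83-fold. Beside Smoc2 and Tagln, Lypd1 fell 3.95-fold, Kank4 3.38-fold and Xkr4 2.77-fold from 15.7 ± 1.05 CPM. Fam177a had a fitted log2 fold change of -5.65 (edgeR adjusted p = 0.0244) that came mainly from regular medium replicate 4, at 152 CPM against 3.28 to 7.31 CPM in the other 3; without that library the value was -2.50 and did not pass (edgeR adjusted p = 0.0803).

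Only the cell cycle list of the 13 that passed camera, 10 up and 3 down, also passed with an estimated correlation. The libraries of the groups did not overlap in 32.7% of the genes tested, where chance alone would give 2.86%.

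**Figure D3:**
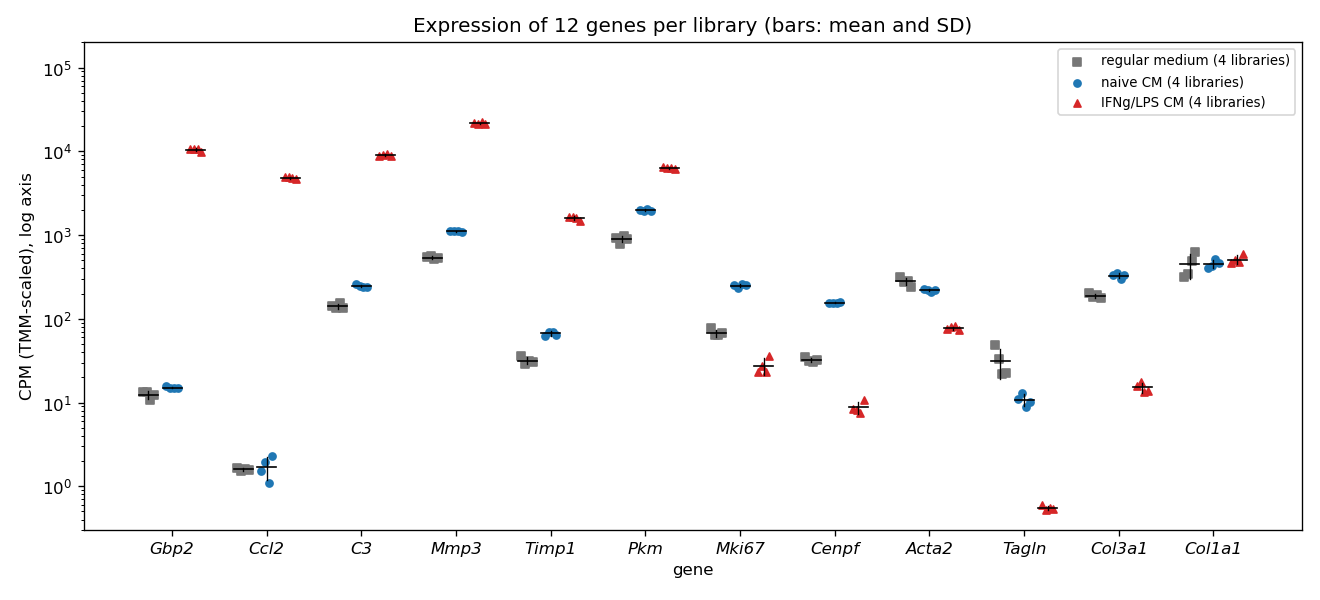
CPM of 12 genes in each of the 12 libraries on a log axis, with squares for regular medium, circles for naive CM and triangles for IFNγ/LPS CM, and bars for the mean and SD of each group of 4. Gbp2, Ccl2 and C3 lie highest in IFNγ/LPS CM, Mki67 and Cenpf highest in naive CM, and Col1a1 overlaps between the groups.

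The comparison of IFNγ/LPS CM with regular medium completes the design and is given as values, since it is the sum of the other contrasts and shares their libraries. Mki67 was 2.47-fold lower, at 27.5 ± 6.26 CPM against 67.8 ± 6.33 CPM, Acta2 3.62-fold lower, at 77.3 ± 3.60 CPM against 280 ± 29.9 CPM, and Tagln, at 0.550 ± 0.0315 CPM, stood against 31.6 ± 12.4 CPM. Mmp3 was 40.1-fold and Timp1 50.3-fold higher, at 21540 ± 547 CPM and 1597 ± 71.4 CPM, and Pkm 7.07-fold higher (mean ± SD, n = 4 each). Among the 44 cell cycle genes 37 were lower, 1 was higher and 6 did not pass. Their median log2 fold change was -0.85 (camera adjusted p = 0.00222, adjusted p = 0.62 with an estimated correlation). This fall was smaller than that against naive CM. In this comparison 11594 genes passed, 5712 higher and 5882 lower, of which 4533 changed by at least 2-fold. With library totals the median of all genes moved from -0.03 to -0.41 and the calls split into 3279 higher and 9597 lower.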

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

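The tests of scaling, of library depth and of adventitial fibroblasts named in this part were chosen only after the result was seen; the test of macrophage carry-over and the splits of the libraries were planned.

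Single libraries stood apart from the other 3 of their group in 43 of 573 groups of 4 values examined, over the named genes, the library totals and the list means, where chance alone gives about 1 in 20, or 29. The value given is the gap to the nearest library as a share of the range of the group. In regular medium replicate 1 was highest for Trem2 (1) and the endothelial list (0.869). Replicate 1 was lowest for Vcam1 (0.871) and Olr1 (0.878). Replicate 2 was highest for Rsad2 (1). Replicate 2 was lowest for Fbln1 (0.851), Acat2 (0.843) and Psat1 (0.87). Replicate 3 was highest for H2-Aa (1). Replicate 3 was lowest for Fabp4 (0.878). Replicate 4 was highest for Mt2 (0.914), Trib3 (0.854), Tek (0.864), Gbp10 (1), Fam177a (0.973) and the cell cycle inhibitor list (0.835).

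In naive CM replicate 1 was highest for Cdkn2c (0.888). Replicate 2 was highest for Pmaip1 (0.849). Replicate 2 was lowest for the protease list (0.852). Replicate 3 was highest for Csf2 (1), Mt2 (0.871), Klf4 (0.96) and Notch3 (0.886). Replicate 3 was lowest for Il18 (0.945). Replicate 4 was highest for Ifi30 (0.899) and Lcp1 (0.863).

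In IFNγ/LPS CM replicate 1 was highest for Gclc (0.903), Trem2 (0.834), Lmod1 (0.879) and the glycolysis list (0.871). Replicate 1 was lowest for Vcam1 (0.935), Hp (0.851) and Ifi27l2a (0.854). Replicate 2 was lowest for Il18 (0.866). Replicate 3 was highest for Mmp13 (0.841). Replicate 3 was lowest for Fosl1 (0.95), Wscd2 (0.834) and Mvd (0.917). Replicate 4 was lowest for Irf1 (0.884), Serpina3f (0.838), Serpina3n (0.844), Csf1 (0.908) and the interferon gamma list (0.836). Several values of 1 come from genes with a count in only 1 library of the group. Apart from those, the highest value was that of Fam177a, at 152 CPM in regular medium replicate 4 against 3.28 to 7.31 CPM in the other 3. No biological explanation was tested for these libraries.

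Interferon-induced genes rose in IFNγ/LPS CM. The planned test of carried-over macrophages or their RNA set the rise of macrophage markers against that of the interferon lists. The summed CPM of the markers rose from 30.4 to 952 CPM (from 30 to 77.7 CPM without Mpeg1). This was 1.19% of the rise of both interferon lists, under the bound of 10% set in advance. Both media came from macrophages, so equal carry-over would also leave the markers unchanged, and this test cannot decide. Ptprc, Adgre1, Tyrobp and C1qa stayed at 3 counts or fewer in every group, which leaves little room for carried-over RNA holding these transcripts. Csf1r, Cd68 and Lyz2 had 656, 881 and 67 counts in IFNγ/LPS CM. Scaling does not explain the rise of the interferon genes, since the median log2 fold change of the type I list was 5.70 with library totals. The data are consistent with a response of the cells to the medium, which may hold interferons made by the treated macrophages, or residual interferon gamma or lipopolysaccharide; these were not told apart.

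Cell cycle genes were higher in naive CM, which held 0.3% serum, than in regular medium. Library depth does not explain this, since the median log2 fold change was 1.59 after all libraries were thinned to the total of the shallowest. Scaling was not tested by the distance of the list from all genes, since one scale factor moves all genes alike. With library totals the median log2 fold change of the list lay 1.62 above that of all genes, and the lower quartile of its members 0.719 above. The list was thus higher relative to genes at large, whatever the scale factor. Growth factors from the macrophages, re-entry into the cycle after starvation and a difference in density or serum could each be the cause, and the design does not separate them.

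Some contractile transcripts were low and others abundant: in regular medium Myh11 stood at 0.717 CPM and Cnn1 at 0.276 CPM, while Acta2 stood at 280 CPM and Tpm1 and Cald1, chosen after their values were seen, at 607 CPM and 808 CPM. Adventitial fibroblasts in the cultures may contribute. The median CPM of the fibroblast list was 0.257 of that of the contractile list in regular medium (1.73 against 6.76), between the bounds set for the test, so fibroblasts and dedifferentiated smooth muscle cells cannot be told apart from these values.

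The splits of the libraries cannot exclude chance as the source of the counts of changed genes. The smallest share that 35 splits allow is 1 of 35. A mixed split also counts the difference between groups as spread within them, which leaves few calls. In fits of the 8 libraries compared, 1 of 35 splits, the real one, called as many genes: 11782 in the first comparison (highest other split 0), 5180 in the second (highest other 2) and 11078 in the third (highest other 0).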

How the results depend on the processing

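The test against a minimum fold of 2 and the fit without the 2 shallowest libraries were chosen only after the result was seen.

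Across the settings other than that test and leaving out single libraries, changed genes numbered 10321 to 12650 in the first comparison, 4456 to 5841 in the second and 10293 to 12876 in the third. Leaving out 1 library gave 11275 to 11449, 4683 to 5624 and 11219 to 11588. Against a minimum fold of 2 the counts were 3670, 179 and 3534, by construction lower. With the replicate block (paired by number) they were 11653, 5780 and 11610.

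Lists that passed numbered 19 in the first comparison and 13 in the second, 18 to 19 and 13 to 14 when 1 library was left out, and 18 and 12 with the replicate block. An estimated correlation left 13 and 1, fry gave 28 and 25 by direction, and fry in either direction gave 30 and 30; fry does not compare a list with other genes. With the replicate block the cytokine list of the first comparison (adjusted p = 0.0642) and the complement (0.435) and fibroblast (0.057) lists of the second lost their calls and the smooth muscle phenotype list of the second gained one (0.0167); the cause was not tested. Without IFNγ/LPS CM replicate 4 the cholesterol list of the first comparison was lost (0.0513), and without regular medium replicate 4 the complement list of the second (0.054).

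Of 3457 values of named genes under alternatives, 3403 kept their side of the threshold, 48 lost the call, 5 gained one and 1 reversed. Of 900 list values 850 kept their side, 24 lost the call and 26 gained one. Values that kept a call also kept its direction. Those not past the test in both settings were counted as kept whatever their direction. The reversed value was mt-Co1 in the first comparison, at -0.18 with library totals, which lower all genes of that comparison by construction. The calls lost most often were those of Fam177a (8 of 16 alternatives) and of Atf3, Adm and Tnfsf18 (7 of 17 each) in the second comparison. In simulated data of the first comparison 70% of 1.5-fold changes were found. The simulation held far fewer changed genes than the real data, so the share missed in the real data is not known.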

Other observations

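All gene lists and single genes in this part were chosen only after values were seen. The adjusted p-values of the lists, taken over these 6 lists only, are therefore descriptive and do not test them.

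Caveola genes fell in IFNγ/LPS CM against naive CM, 8 of 8 lower (median log2 fold change -0.96; camera adjusted p = 5.21e-05, 0.00967 with an estimated correlation), and iron handling genes rose, 9 higher and 4 lower of 14 (median 1.54; camera adjusted p = 1.95e-06, 0.00987 with an estimated correlation). Fatty acid oxidation genes (median -0.17; camera adjusted p = 0.196), circadian clock genes (0.23; 0.462), prostanoid genes (1.29; 0.204) and constitutive proteasome genes (0.33; 0.196) did not pass. In naive CM against regular medium the proteasome genes (median 0.16; camera adjusted p = 0.00712, 0.337 with an estimated correlation), iron handling genes (0.12; 0.0231, 0.164 with an estimated correlation) and caveola genes (-0.18; 0.0477, 0.164 with an estimated correlation) passed, and the fatty acid oxidation (0.269), clock (0.761) and prostanoid (0.269) lists did not.

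Some macrophage-associated transcripts rose in IFNγ/LPS CM while others stayed near 0. Csf1r stood at 4.62 ± 0.515 CPM against 0.203 ± 0.0873 CPM in naive CM, Cd68 at 6.19 ± 1.1 CPM against 1.07 ± 0.170 CPM and Lyz2 at 0.472 ± 0.153 CPM against 0.0785 ± 0.0888 CPM (mean ± SD, n = 4 each).

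In regular medium abundant structural transcripts were Vim at 2360 CPM, Flna at 2080 CPM, Dcn at 1670 CPM, Myl6 at 902 CPM, Cald1 at 808 CPM and Tpm1 at 607 CPM.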
